A study of Rattus norvegicus with 10 samples.

How the data were processed

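The study measured polyadenylated RNA of the whole hippocampus by sequencing in 10 adult male rats, 5 of the bred High Responder line (bHR) and 5 of the bred Low Responder line (bLR), which were selectively bred for high and low locomotor response to novelty. Per the labels' protocols, all rats came from generation 43, received vehicle injections for 14 days under standard housing, and were used at postnatal day 92. The tissue was taken 1 hour after a test on the elevated plus maze. Each rat also has a social interaction score in the labels, measured after 15 minutes on that maze. The labels give the score no unit. The rats are separate animals, so the p-values of the comparisons between lines and of the score measure the spread between animals. The p-values from random draws of genes or gene pairs do not.

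Libraries were made with a kit that keeps strand and sequenced as single reads of 50 bases, described as non-stranded, from RNA with an integrity number above 8, per the labels' protocols. Reads were aligned to Rnor_6.0 with Subread without indel detection and counted per gene with featureCounts on Ensembl release 85, per the labels' protocols. The strand setting of the counting is not given in the sources used here, so a gene and an antisense or overlapping partner may share reads. Genes were kept with at least 16 counts in at least 5 samples and turned into log2 values with limma voom in R 3.2.2, per the submitters' processing notes and the labels' protocols. Of the 16643 genes, 505 did not meet that filter over these 10 libraries, 4 of them among the genes called below as changed between lines. Whether the filter was applied over the larger study is not given in the sources used here. The deposited table holds 16643 genes as log2 RPM (reads scaled to a common library size), 1 column per rat, and the authors' values follow the voom form, the log2 of the reads plus 0.5 after division by an effective library size. No columns of per-sample values were left unused.

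Whole reads were recovered from the deposited log2 values: a single constant per library turned 100.0% of the values into whole numbers within a tolerance of 0.01 reads. The same step recovered 100.0% of simulated values. The authors' effective library sizes lay between 0.933 and 1.02 times the totals of these reads, as a scaling factor per library would give. No factor is stated in the sources used here. No pair of libraries of the same line agreed within sampling noise: over 20 pairs the chi-square per gene was 6.10 or more, against about 1 for sampling noise, and 0 pairs held identical values.

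The lines were compared with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with the line as the only term, an intensity trend in the prior variance, and Benjamini-Hochberg adjustment over all 16643 genes at 0.05. Differences are bHR minus bLR. The association with the social interaction score was tested in a limma model with line and score together. Scores were compared by an exact permutation test over 252 assignments. Principal components were computed on the centred log2 values, and the first 4 were compared between the lines by exact permutation tests with Benjamini-Hochberg adjustment. In data simulated with the means, library sizes and spread of these libraries, with 200 of 16643 genes changed, the line model recovered 30% of 50 genes changed 1.2-fold, 70% at 1.5-fold, 86% at 2-fold and 98% at 4-fold. Of 148 calls in that simulation, 6 were false. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

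The designs, the alternatives, the gene lists and the rule for named genes were written before the data were examined. The rule took genes with an adjusted p under 0.05, a gene symbol, a mean log2 value of at least 0 and lines that do not overlap, ordered by fold change, 10 per direction, and filled up by the smallest p. It added up to 4 members per gene list, the members of a list of genes from earlier work on these lines, and 3 genes per direction for the score. The files do not pair the identifiers with gene names, and 0 of 16643 identifiers matched the table of rat RefSeq genes (GRCr8). The rule was therefore applied without the symbol, and the 2 identifiers with the largest change in each direction are printed. The tests of gene lists, which needed symbols, and the correction for GC content and the test of chromosomal clustering, which needed Rnor_6.0 annotation, were not run. The order of rows in the deposited table was used for a test of neighbouring genes chosen after seeing the data.

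The alternatives covered the variance prior, a filter at a mean log2 value of 1, 2 other normalizations, library weights, a prior count of 2 reads, voom weights on the recovered reads, the replicate number as a block, the score as a covariate, other thresholds, and leaving out each library in turn. The principal components, scaling to total reads and leaving out genes high in 1 library were added after seeing the data.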

Results

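Hippocampal gene expression was measured in 10 adult male rats from lines selectively bred for a high (bHR) or low (bLR) locomotor response to a new environment, with 5 rats per line. All were vehicle-treated controls from a larger study of antidepressants and chronic stress. The libraries held 29106105 to 48663164 reads assigned to the 16643 genes in the table, with means of 39114678 ± 7486310 reads (SD, n = 5) in bHR and 33759218 ± 5216970 in bLR. Across genes, log2 values correlated with Pearson's r of 0.989 to 0.994 between bHR rats, 0.984 to 0.991 between bLR rats and 0.983 to 0.990 between lines. Genes are not independent replicates.

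The first comparison asked whether the lines differed in social behaviour under an anxiogenic condition. The bHR rats had a mean social interaction score of 22.2 ± 4.91 (SD, n = 5) and the bLR rats 13.2 ± 6.71 (n = 5), a difference of 9.0 points. Scores ran from 16.67 to 28.33 in bHR and from 7.33 to 24.0 in bLR, so the lines overlapped through bLR replicate 4. The two-sided exact permutation test gave p = 0.048 over 252 assignments, where the smallest possible p was 0.0079. The difference of medians, 11.67 points, gave an exact p of 0.12, and leaving out any 1 of 7 rats (bHR replicate 1, 4 or 5, or bLR replicate 1, 2, 3 or 5) took p above 0.05, to at most 0.10.

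**Figure D1:**
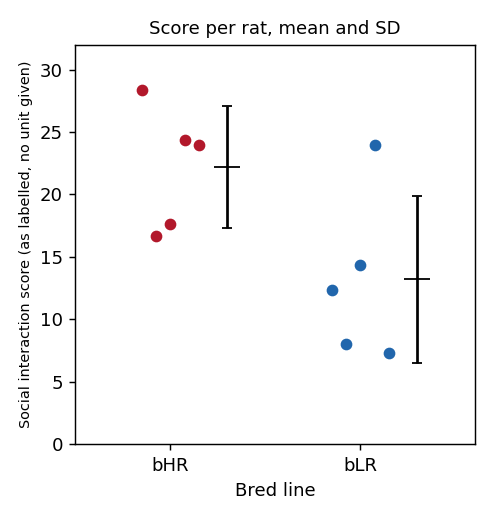
Social interaction score of each rat (points, score as labelled, no unit given) by bred line, with the mean and SD beside them (bars). The bHR rats lie between 16.67 and 28.33 and the bLR rats between 7.33 and 24.0, with 1 bLR rat inside the bHR range.

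The second comparison asked which hippocampal transcripts differed between the lines. Of 16643 genes, 102 were higher and 128 lower in bHR than in bLR, 230 in all (limma, Benjamini-Hochberg adjusted p under 0.05). The typical difference was small: the median absolute log2 fold change of the changed genes was 0.43, and 153 of them differed by less than 1.5-fold. At the other end, 32 changed genes differed at least 2-fold, 13 higher and 19 lower in bHR, and 14 differed at least 4-fold, 7 in each direction. The largest change was 5.21 on the log2 scale, in a gene where bLR replicate 2 lay inside the bHR range. In 219 of the 230 genes the 5 bHR rats and the 5 bLR rats did not overlap. Over all genes 691 were separated in this way, 332 higher and 359 lower in bHR, against 132 (0.794%) given by chance.

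The changed genes spanned the range of transcript abundance, and the size of the difference fell with abundance. Among the 4161 least abundant genes 46 changed, 15 higher and 31 lower in bHR, with a median absolute log2 fold change of 1.13. Of the next 4161 genes by abundance 61 changed (28 higher, 33 lower, median 0.50), and of the 4160 after those 73 changed (30 higher, 43 lower, median 0.34). Of the 4161 most abundant genes 50 changed, 29 higher and 21 lower, with a median of 0.23. Low-abundance genes vary more between libraries and need a larger difference to pass the test, so these medians are not free of the threshold. Of the 14 genes changed at least 4-fold, 9 had a mean log2 value below 0.

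**Figure D2:**
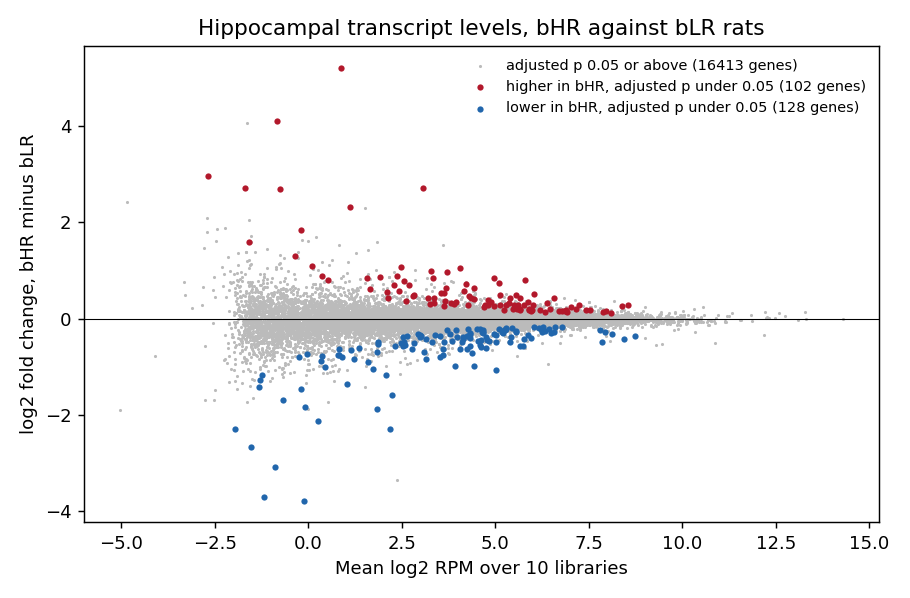
Fold change between lines (log2, bHR minus bLR) of each gene against its mean log2 RPM over the 10 libraries. Coloured points are the 102 genes higher and the 128 genes lower in bHR at an adjusted p under 0.05, and grey points are the other genes.

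The deposited files do not pair the gene identifiers with names, so 2 identifiers per direction are given. ENSRNOG00000025639 was higher in bHR, at 22.2 ± 7.50 RPM (reads scaled to library size, SD, n = 5) against 3.31 ± 0.62 in bLR, a log2 fold change of 2.71 (SE 0.19, limma adjusted p = 3.4e-05). Its reads numbered 497 to 1602 in the bHR libraries and 86 to 159 in the bLR libraries. ENSRNOG00000018906 was lower in bHR, at 2.07 ± 0.25 RPM against 10.01 ± 0.68 in bLR, a log2 fold change of -2.28 (SE 0.10, limma adjusted p = 3.8e-07), from 57 to 112 reads against 257 to 465. Both calls held in all 22 alternative settings.

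The other printed identifiers lay close to the threshold. ENSRNOG00000002911 was higher in bHR, at 4.85 ± 0.60 RPM against 1.41 ± 1.42 in bLR, with a log2 fold change of 2.32 (SE 0.51, limma adjusted p = 0.0499). The bLR rats were uneven, with 13 to 139 reads, the highest being in replicate 1. ENSRNOG00000058611 was lower in bHR, at 0.68 ± 0.36 RPM against 2.52 ± 0.37 in bLR, with a log2 fold change of -2.13 (SE 0.41, limma adjusted p = 0.030) and 6 to 56 reads against 66 to 113. In the alternatives their limma adjusted p ranged from 0.0036 to 0.12 for ENSRNOG00000002911, which passed in 8 of 22 settings, and from 0.0073 to 0.23 for ENSRNOG00000058611, which passed in 13 of 21. The log2 fold changes kept their direction, from 2.05 to 2.82 and from -2.38 to -1.69.

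**Figure D3:**
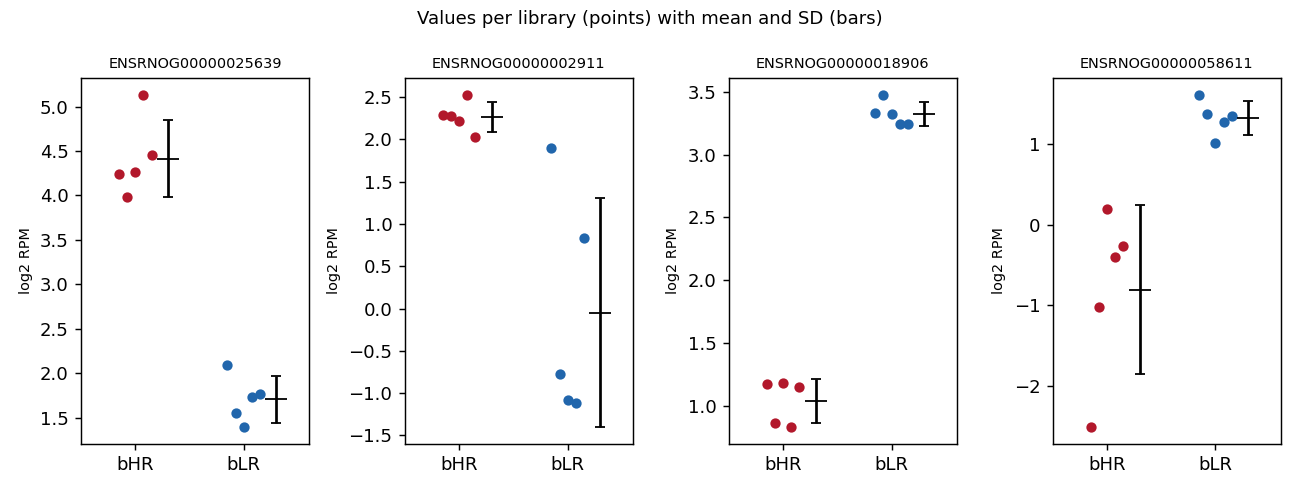
Log2 RPM of the 4 printed identifiers in each bHR and bLR library (points), with the mean and SD of the line (bars). The lines do not overlap for any of the 4, which was a condition for printing them. The gap is narrowest for ENSRNOG00000002911, where bLR replicate 1 had 139 reads.

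The number of changed genes depended on which rat was left out and on the model. Leaving out bHR replicate 1, 2, 3, 4 or 5 gave 135, 109, 108, 115 or 175 genes, and leaving out bLR replicate 1, 2, 3, 4 or 5 gave 182, 121, 138, 213 or 216. With the social interaction score as a covariate, which shares its variation with the line, 46 genes passed. Scaling each library to its total reads in place of the authors' effective size turned the balance, with 57.7% of 194 changed genes higher in bHR against 44.3% of 230. The balance was near even with median-shifted libraries (49.8% of 211 genes higher in bHR) and with quantile normalization (49.8% of 223). The bLR replicate 5 library had an effective size of 0.933 times its total reads, against 1.00 to 1.02 in the others, and its most abundant gene took 4.06% of its reads, a gene that took 0.26 to 0.49% in the others. The most abundant gene of each other library took 1.92 to 2.14%. Of the 216 genes that passed without that library, 156 were among the 230.

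The lines were also compared over all genes together. The first principal component held 20.8% of the variance, and all 5 bHR rats lay on the other side of it from all 5 bLR rats (two-sided exact permutation p = 0.0079, the smallest possible, and 0.032 after Benjamini-Hochberg adjustment over 4 components). The second held 19.0% and did not separate the lines (exact p = 0.51). The first component did not separate the lines when libraries were scaled to their total reads (exact p = 0.93), and with genes below a mean log2 value of 1 removed it gave an exact p of 0.056. In the 4 other settings tried it did (exact p = 0.0079 in each): median-shifted libraries, quantile normalization, a prior count of 2 reads, and without the genes high in bLR replicate 5. Only the first component was compared in these settings, so a loss of separation cannot be told from a change in the order of components.

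**Figure D4:**
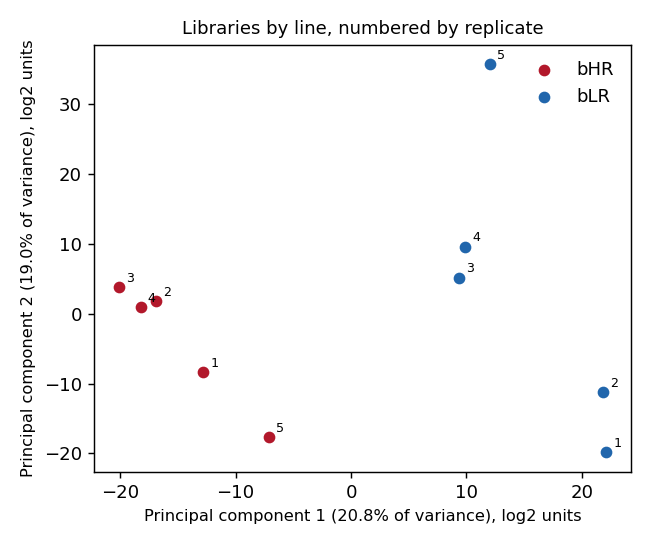
Libraries on the first and second principal components of the log2 values, in log2 units, coloured by line and numbered by replicate. The lines separate on the first component (20.8% of the variance). On the second (19.0%) bLR replicate 5 is highest, at 35.7 against at most 9.6 in the others. It was not an outlying value of its line there by the rule used below.

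The third comparison asked whether transcript levels followed the social interaction score among rats of the same line. No gene passed in the limma model with line and score, a count of 0 with a smallest adjusted p of 0.62. At an unadjusted p under 0.05 there were 1183 genes, 516 rising and 667 falling with the score, against 832 expected with no effect, and limma with voom weights also gave 0. Without the intensity trend 1 gene passed (limma adjusted p = 0.035). Without bLR replicate 4, the bLR rat with the highest score, the unadjusted number was 591. Leaving out any other single rat gave 995 to 1467.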

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

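The tests on the genes high in bLR replicate 5, and some of the measures searched for outlying values, were chosen after the result was seen. A single outlying value was looked for within each line, in 32 groups of 5 values: the social score, total reads, effective size over total reads, genes at 0 reads, the shares of the most abundant gene and of the 10 most abundant genes, the lowest, highest and median log2 value, the within-line spread, principal components 1 and 2, and the 4 printed identifiers. There were 4 such values, all in bLR replicate 5. By chance about 1 in 20 groups would hold such a value, and 32 groups were searched. The 4 are not independent, since the most abundant gene enters both shares and is the highest value. Its effective library size was 0.933 times its total reads, with the nearest other bLR library at 1.00, and its most abundant gene took 4.06% of its reads, where the most abundant gene of the nearest other bLR library took 2.14%. The gene itself took 0.26 to 0.49% of the reads in the other 9 libraries. The 10 most abundant genes of bLR replicate 5 took 13.04% of its reads, with the nearest other bLR library at 8.72%, and its highest log2 value was 15.41, with the nearest at 14.37.

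These values go with a set of 45 genes that lay over 3 log2 units above the median of the other libraries, by a median of 4.58, where each other library had 2 to 9 such genes. It includes the most abundant gene of that library. The rise was present in the recovered reads before any scaling: the set took 7.86% of the reads in bLR replicate 5 and 0.49 to 0.84% in the other 9 libraries. The set was picked for its high values in that library, whose effective size was near its total reads. A higher share therefore followed from the selection and is not independent evidence against an error of scaling. The level of the whole library does bear on it, since a scaling factor moves all genes of a library alike. The median log2 value over all 16643 genes was 4.103 in bLR replicate 5 and 4.095 to 4.121 in the other libraries. This argues against an error of scaling as the source of the rise in these 45 genes. The set also varied together in the other 9 libraries, with a median pairwise correlation of 0.46 where the highest of 10000 random sets of similar abundance reached 0.10 (p = 0.0001, the smallest the draws can give), so 1 shared source of reads present in every library in differing amounts is a candidate explanation. The source cannot be named because the files do not pair identifiers with names, no biological explanation was tested, and 2 of the 45 genes were among the 230 changed between lines.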

How the results depend on the processing

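The settings with total-read scaling, without the 45 genes, all those of the first principal component and the row windows were chosen after seeing the data. The 230 genes changed between lines became 152 without the intensity trend (138 shared), 46 with the score as a covariate (37 shared), 503 at an adjusted p under 0.10 and 77 with at least 1.5-fold. Leaving out 1 library gave 108 to 216 genes, depending on the library, with at least 101 shared. The other settings without a block stayed within 1.5 times. Without the 45 genes 237 passed, and total-read scaling gave 194 genes, 57.7% higher in bHR against 44.3%. With median-shifted libraries and with quantile normalization 49.8% were higher in bHR. The same replicate numbers do not pair the rats: same-number correlations ran from -0.15 to 0.15, and 1 of 5 bHR libraries correlated best with its own number. With the replicate block 108 genes changed, 95 shared, 1 gene followed the score, and the social score difference of 9.0 had an exact sign-flip p of 0.063, the smallest possible. The score difference was 11.67 for medians (exact p = 0.12) and ran from 7.47 to 11.70 without 1 rat (exact p = 0.016 to 0.10). For genes following the score, 1 passed without the trend and 0 in the 21 settings other than this and the block. For changes in settings with all libraries the cause was not tested. The gene list tests, GC correction and chromosomal windows were not run. At the depth and spread of these libraries simulated 1.2-fold changes were recovered in 30% of cases, and the part of depth in this was not tested.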

Other observations

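The test of other splits of the libraries, the tests of opposite-direction pairs and of crowded rows, and the row windows were chosen after the results were seen. The real split by line gave 230 changed genes, and among 100 of the 126 possible splits of the 10 libraries into 5 and 5, only 1, the real one, gave as many. The highest of the others gave 2, and 1 in 100 is the strongest result these splits can give. Each of the others put rats of both lines in each group, so a line difference would add to the spread within its groups and lower its count. Their counts are therefore not an estimate of the false calls among the 230. Without any line difference, though, the real split would rank first no more often than any other split. Its rank, 1 in 100, thus argues against a random split as the source of the count.

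The changed gene with the largest fold change, chosen after its values were seen, had 2 to 7 reads in 4 of the 5 bLR rats and 264 to 660 in the bHR rats. Its log2 value was 2.94 to 4.16 in bHR, with a log2 fold change of 5.21 (SE 1.04, limma adjusted p = 0.035). In bLR replicate 2 it was 3.04 (344 reads), inside the bHR range, while the other 4 bLR rats lay between -3.72 and -1.96. A smaller difference within the line was seen in ENSRNOG00000002911, where bLR replicate 1 had a log2 value of 1.90 (139 reads) and the other bLR rats lay between -1.12 and 0.83 (13 to 48 reads).

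Changed genes lay near each other in the row order of the deposited table, which carries no positions. Of the 230, 31.3% had another changed gene within 5 rows, against a mean of 12.9% in 10000 random draws (permutation test), and the excess held at 1, 2, 10 and 20 rows but not at 50 (p = 0.15). Uneven abundance along the rows is argued against by draws matched on abundance (permutation p = 0.0001, the smallest they can give). Pairs changed in opposite directions numbered 14 against 7.83 in draws (permutation p = 0.029). Those draws did not keep the clustering, which raises pairs of either kind, so this count cannot decide about reads shared between overlapping or duplicated genes. The 41 pairs changed in the same direction (7.95 in draws) varied together within lines. Their median residual correlation was 0.25 against 0.01 for distant pairs (permutation p = 0.0016). Some of the close pairs share a gene, which the draws of distant pairs did not match, so this p may be too small. Shared reads or joint regulation of neighbours may account for the same-direction pairs. Linked segments that differ between the lines stay open as well: 7 changed genes, all lower in bHR, lay within 10 rows, where the draws reached at most 5, and without gene positions this cannot be decided.

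Rats of the bLR line differed more from each other than bHR rats did. The median absolute deviation of a library from its line mean over 13796 genes averaged 0.077 ± 0.0075 log2 units (SD, n = 5) in bLR and 0.059 ± 0.0061 in bHR, a difference of 0.018 (two-sided exact permutation p = 0.016). This comparison was not among the designs written beforehand. The 5 values of a line share its mean and are not independent, so this p and those below are approximate and may be too small. Fewer reads in bLR are argued against, since thinning all libraries to 29106105 reads left a difference of 0.016 (exact p = 0.016), and so is bLR replicate 5 alone, since the difference was 0.018 without it (exact p = 0.0079). With the first principal component of each line removed it was 0.016 but within the spread of the libraries (exact p = 0.087), so a single axis of variation in each line stays open. A line difference in variability between animals remains an untested hypothesis.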
